A study of Arabidopsis thaliana with 12 samples.

How the data were processed

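The 12 arrays measured total RNA from whole Col-0 seedlings, stratified for 2 days at 4 °C and grown for 5 days at 21 °C with 18 h of light and 6 h of dark, per the labels' protocols. The RNA was copied with an oligo-dT primer and labelled by in vitro transcription, so that transcripts are read near their 3′ end. The deposited table holds 1 log2 expression value per probe set and array, from 3.13 to 14.63, already normalized by the authors. The submitters' processing notes name RMA and limma without versions, and the background correction and the summary of probes were theirs. RMA as such a method quantile-normalizes arrays together, and the deposited values carry no detection calls. The array medians lay between 6.39 and 6.53, and no 2 arrays were copies: within a genotype at most 2 of the 22810 values were identical between 2 arrays.

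Groups were taken from the titles, with replicate numbers 2, 3 and 4 in each of the 4 genotypes, which the labels call biological replicates. The description field of the scrm-D samples names the double mutant, whereas their titles and genotype fields name scrm-D, and the latter were used. Bacterial control transcripts separated the 4 labelled genotypes on all 12 arrays, as given in the closing section.

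The 64 control probe sets were left out, which left 22746. The log2 values as deposited were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per genotype over all 12 arrays and default empirical Bayes moderation (prior degrees of freedom 4.41). The tests were two-sided, with Benjamini-Hochberg adjustment over the probe sets of each comparison, and a probe set was called at an adjusted p under 0.05. Unless named otherwise, an adjusted p of a gene is limma's, a change after "by" is on the log2 scale, and its error is a standard error. Where 1 of the 2 groups lay under the background level, the 95th percentile of absent controls (4.95), the fold was taken against that level and is written as at least, a choice made after the data were seen, while the order of the largest changes follows the fitted values. Between genotypes 35.1%, 30.0%, 41.4% and 28.4% of the probe sets had 3 values all above or all below the 3 of the other group, in the order spch, scrm-D and the double mutant against WT and the double mutant against scrm-D, where chance gives 10%. The median log2 change over all probe sets lay between −0.01 and 0.00223, so changes are relative to a total held constant.

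Probe sets were named through the platform annotation given with the data. It pairs 13513 of the 22810 probe sets with 1 gene and 503 with several, and 8794 are unlisted and thus unnamed here. Of the single-gene probe sets, 13436 matched the locus of the reference annotation TAIR10.1, which was used for symbols only. A genome build for the probe sets is not given in the sources used here, so no coordinates are printed. The rule for the genes named, not the genes, was fixed before the data were examined. It takes the 8 largest rises and 8 largest falls of each comparison among called single-gene probe sets with non-overlapping groups, up to 4 members of each list by adjusted p, the 8 leading genes of each of 4 patterns, and SPCH, MUTE and SCRM. SCRM had no single-gene probe set in that annotation and was not analysed here. Genes in the closing section that come from groupings made after the data were seen fall outside it. A gene with several probe sets was represented by the one with the highest mean.

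The 16 gene lists, with 271 members, were also fixed before the data were examined and cover the stomatal lineage, guard cells, cell cycle, epidermis, mesophyll, root, meristem, cold, hormones, defence, pigments and the clock. Only 36 members had a named probe set, so a list is represented by few genes and 1 list by none. Lists of at least 3 measured genes, a minimum chosen once this coverage was known, were tested with limma's camera at its preset correlation of 0.01, and the 28 tests (7 lists in 4 comparisons) were adjusted together. All 11 calls of these set tests were lost with the correlation estimated from the data.

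The design without a block is the main one. Whether the replicate numbers pair arrays was checked by correlating deviations from the genotype means between arrays of the same number, with a limit of 0.1 for every pair. The correlations were 0.138, 0.173 and 0.174 for spch with WT, 0.103, 0.299 and 0.214 for scrm-D with WT, and 0.260, 0.215 and 0.525 for the double mutant with scrm-D, which counts as pairing. For the double mutant with WT they were 0.0826, 0.130 and 0.250, which does not. Between arrays of different numbers the correlation reached 0.102 for spch with WT and 0.177 and 0.140 for the double mutant with scrm-D, also over the limit. For scrm-D with spch, not reported as a comparison, it reached 0.196 and 0.230 where the same numbers gave 0.0338 and 0.134, so the numbers are an uncertain guide to pairing. The labels do not say what a number marks, so the pairing comes from the values alone.

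On simulated data with 200 of 22746 probe sets changed, the fit recovered 86% of those changed by log2 1 and 100% of those changed by log2 2 for spch against WT, with 6 false calls. The shares were 94% and 100% for scrm-D against WT (8 false calls), 92% and 98% for the double mutant against WT (8), and 91% and 99% for the double mutant against scrm-D (10). Overlaps between comparisons that share WT were set against 20 simulated data sets, whose arrays vary independently of the replicate number, and against independent lists.

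Alternatives were median centring, quantile normalization, leaving out the dimmest 40% of probe sets or those marked as cross-hybridising, moderation with trend and robust settings, array weights, the replicate number as a block, a fit on the 2 groups compared, an adjusted p under 0.01, an estimated correlation for the set tests, and each array left out in turn. Leaving out replicate 4 of every genotype, the 25S rRNA control as a covariate and the set tests without each array were added after the data were seen.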

Results

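Gene expression was measured on 12 Affymetrix arrays in whole Arabidopsis thaliana seedlings of the Col-0 ecotype, harvested 5 days after germination, with 3 biological replicates in each of 4 genotypes. Stomata, the pores of the plant epidermis, arise from a cell lineage whose self-renewing precursor, the meristemoid, later gives rise to a pair of guard cells. SPCH, MUTE and FAMA are transcription factors that act in that order along the lineage, and scrm-D is a dominant allele of SCRM, which encodes their partner. The labels describe the spch epidermis as made of pavement cells alone, that of scrm-D as guard cells, and that of scrm-D;mute, called the double mutant here, as nearly all meristemoids. Wild type (WT) seedlings served as the control. The median log2 value of an array lay between 6.39 and 6.53. Across probe sets, which are not independent replicates, arrays of the same genotype correlated with r between 0.986 and 0.995, and arrays of different genotypes with r between 0.935 and 0.977. The number of arrays limits the precision, and p-values measure the spread between these samples only.

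SPCH (AT5G53210) read between 6.15 and 6.71 on the log2 scale on the WT arrays, between 5.11 and 5.41 on the spch arrays and between 10.56 and 10.89 on the double mutant arrays, with a mean of 7.57 ± 0.53 (SD, n = 3) in scrm-D. It was 2.08-fold lower in spch than in WT (log2 change −1.05 ± 0.23 SE, adjusted p = 0.00726), 2.31-fold higher in scrm-D and 21.2-fold higher in the double mutant. MUTE (AT3G06120) read between 4.42 and 4.52 in WT, between 4.05 and 4.39 in spch, between 6.57 and 7.58 in scrm-D, with a mean of 10.78 ± 0.20 in the double mutant. MUTE was at least 4.21-fold higher in scrm-D than in WT and at least 56.6-fold higher in the double mutant, folds taken against the background level of 4.95 because WT lay under it. MUTE did not pass the test in spch (adjusted p = 0.421). Control probe sets on arrays that lacked their spiked transcript read up to 5.88, with a median of 3.99 and a 95th percentile of 4.95, a range that holds the spch values of SPCH and the WT and spch values of MUTE. The positions of the spch and mute lesions relative to the probe sets are not given in the sources used here, and a probe set outside the changed part checks nothing about a label. SCRM was not analysed here.

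**Figure D1:**
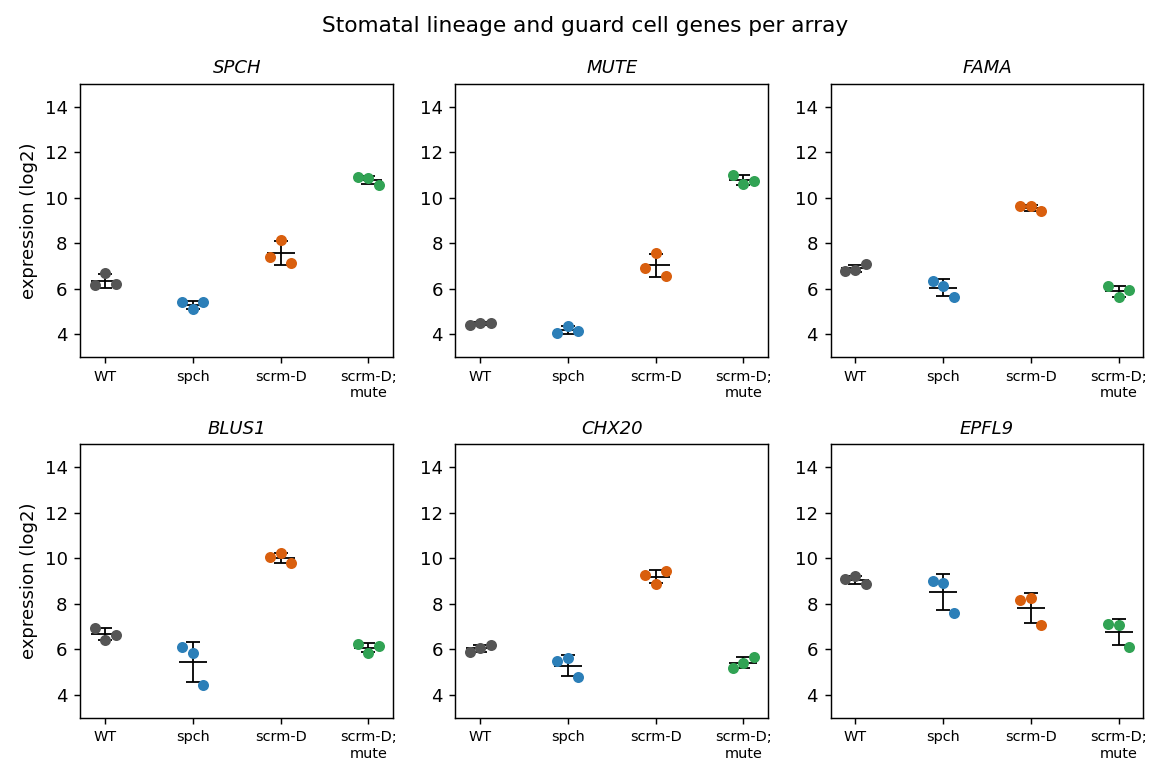
Expression (log2) of SPCH, MUTE, FAMA, BLUS1, CHX20 and EPFL9 on each array, with 1 point per array, the mean as a long line and 1 SD as bars (n = 3 per genotype). SPCH and MUTE were highest in scrm-D;mute, with means of 10.77 and 10.78, whereas FAMA, BLUS1 and CHX20 were highest in scrm-D.

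In spch, whose epidermis per the labels holds pavement cells alone, genes of cell division, guard cells, anthocyanin synthesis and cold response were among those that fell, and glutaredoxin genes were among the largest rises. Here and below, the largest rises and falls are those among called single-gene probe sets with non-overlapping groups, not among all probe sets. AT1G19530 rose at least 20.8-fold against background, from 4.27 ± 0.10 in WT to 9.33 ± 0.22 (SD, n = 3, adjusted p = 1.78e-06). The glutaredoxin genes AT4G15660, AT4G15680, AT4G15690 and AT4G15700 rose at least 14.0-fold, 16.2-fold, 14.5-fold and at least 11.3-fold, and AT3G62950, a further glutaredoxin gene, rose at least 7.94-fold. These are related sequences, so their probe sets may share signal. The largest falls were in the thionin gene AT1G66100 (17.5-fold, from 10.97 to 6.84), COR15A (AT2G42540, 17.0-fold), the defensin gene PDF2.1 (AT2G02120, 10.9-fold) and the dirigent gene AT4G11190 (10.8-fold). AT5G03350, which encodes a lectin, and AT1G73600, which encodes a methyltransferase of phosphocholine synthesis, fell by 3.03 and 3.03 on the log2 scale.

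Of the 27 listed genes of G2 and mitosis, 3 were measured and all 3 fell in spch: the Aurora kinase genes AUR1 (AT4G32830), AUR2 (AT2G25880) and AUR3 (AT2G45490), by 1.44, 1.37 and 0.54. All 3 also passed when adjusted over the list alone, and the set test gave adjusted p = 0.00128, but adjusted p = 0.183 with an estimated correlation. The AUR3 call ended without any 1 of 4 arrays (WT replicates 3 and 4, spch replicates 2 and 4), with adjusted p from 0.0708 to 0.0825. Both measured genes of DNA replication and S phase fell, PRL (AT4G02060), a subunit of the replicative helicase, by 0.64 and CENH3 (AT1G01370), the centromeric histone, by 0.71, and both passed when adjusted over the list alone. PRL gave adjusted p = 0.0544 without spch replicate 4, and CENH3 gave 0.0687 without that array and 0.0721 without WT replicate 3. Among the 3 measured guard cell genes, FAMA (AT3G24140) fell by 0.86 and BLUS1 (AT4G14480), a kinase of blue light-driven stomatal opening, fell 2.30-fold. The third, GC1 (AT1G22690), differed by −2.78 ± 1.08 (adjusted p = 0.0976, and 0.0463 with the replicate number as a block), with 4.31 on spch replicate 4 against 9.64 and 9.70 on the others, and passed without spch replicate 2 or 3 (0.0450 and 0.0460). All 3 guard cell genes passed when adjusted over the list alone. BLUS1 and FAMA were also lowest on spch replicate 4, at 4.5 and 5.6. On spch replicates 2 and 3 BLUS1 read 6.1 and 5.8, and FAMA 6.4 and 6.1. GC1 on those 2 arrays lay nearer to its WT values (10.38 to 10.86) than to spch replicate 4. That level sits badly with an epidermis of pavement cells alone, unless other cells express GC1, which was not tested. The split was not confined to GC1. On spch replicates 2, 3 and 4, AT1G33811 read 8.49, 8.29 and 4.24 and AT5G25840 read 7.22, 6.93 and 4.51, both genes being higher in scrm-D than in WT. AT4G18280 (6.91, 6.69 and 6.58) and AT2G32190 (4.35, 4.27 and 5.07), also higher in scrm-D, were not lower in this way on replicate 4. What sets that array apart was not tested. The guard cell set test gave adjusted p = 0.0289, and adjusted p = 0.294 with an estimated correlation. BLUS1 gave adjusted p = 0.0810 without WT replicate 2, 0.0525 without WT replicate 4 and 0.0652 in a fit of the spch and WT arrays alone. Of the 3 measured stomatal lineage genes only SPCH fell (1 when adjusted over the list alone), and EPFL9 (AT4G12970), a peptide that promotes stomatal formation, differed by −0.55 ± 0.40 (set test, adjusted p = 0.127).

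Both measured genes of anthocyanin synthesis fell in spch, DFR (AT5G42800) at −3.32 and UF3GT (AT5G54060) at −2.46, and both passed when adjusted over the list alone. In the cold response list, COR15A fell by 4.09 and COR15B (AT2G42530) by 3.10, both encoding chloroplast proteins of freezing tolerance, and 2 of 5 passed when adjusted over the list alone. COR47 (AT1G20440), LTI30 (AT3G50970) and ZAT10 (AT1G27730) did not pass, at −0.12, 0.33 and 1.16, and the set test gave adjusted p = 0.376. It was 0.0264 without replicate 4 of every genotype, a setting chosen after the data were seen. Without WT replicate 2 COR15B gave adjusted p = 0.0508 and ZAT10 0.0357, and without WT replicate 3 COR15B gave 0.0650. The root hair expansin genes EXPA18 (AT1G62980) and EXPA7 (AT1G12560), the measured markers of root cell types, fell by at least 1.55 and by 0.92, and both passed when adjusted over the list alone. In the auxin list IAA29 (AT4G32280) fell by 0.70 and GH3.3 (AT2G23170) by 0.80, 2 of 3 when adjusted over the list alone (set test, adjusted p = 0.211). The EXPA7 call ended without any 1 of the WT and spch arrays or replicate 3 of the double mutant (adjusted p from 0.0566 to 0.148), and the GH3.3 call without any 1 of these except WT replicate 4 (0.0583 to 0.163). The 5 measured photosynthesis genes differed by −0.52 to 0.20 with no call, none when adjusted over the list alone, and the set test gave adjusted p = 0.976 in the upward direction while their median was −0.01. LHCB4.2 (AT3G08940), at −0.52, gave adjusted p = 0.0764, 0.0101 with the replicate block, 0.0371 without replicate 4 of the double mutant and 0.0443 without scrm-D replicate 4. The 3 defence genes differed by −0.85 to −0.01 with no call, none when adjusted over the list alone (set test, adjusted p = 0.498), and PDF1.2 (AT5G44420), at −0.85, gave 0.0417 without scrm-D replicate 3.

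Over all probe sets, limma called 4442 of 22746 (19.5%) between spch and WT, 2183 higher and 2259 lower, of which 563 and 548 changed at least 2-fold. Unlisted probe sets, which could not enter the rankings, made up 2040 of the 4442. The 25S rRNA control probe set read 9.63 ± 1.25 in spch and 7.11 ± 0.49 in WT (SD, n = 3), and with that value as a covariate, a setting chosen after the data were seen, 2108 probe sets were called. The calls of FAMA, BLUS1, AUR3, PRL, CENH3, EXPA7, GH3.3 and the guard cell list then ended, with adjusted p = 0.0825, 0.256, 0.0816, 0.0570, 0.152, 0.418, 0.333 and 0.0903. AUR3 and PRL were not smaller with the covariate, at −0.60 ± 0.19 against −0.54 ± 0.15 (SE) without it and −0.70 ± 0.21 against −0.64 ± 0.16, and their calls ended with the wider error. The other 5 genes were smaller and had wider errors, FAMA at −0.66 ± 0.22 against −0.86 ± 0.18, BLUS1 at −0.79 ± 0.39 against a 2.30-fold fall with a log2 error of 0.33, CENH3 at −0.59 ± 0.23 against −0.71 ± 0.18, EXPA7 at −0.50 ± 0.33 against −0.92 ± 0.29 and GH3.3 at −0.56 ± 0.32 against −0.80 ± 0.25. The 25S rRNA control read 11.04 on spch replicate 4 against 8.66 and 9.19 on spch replicates 2 and 3. Without spch replicate 4, 2955 probe sets were called.

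In scrm-D, whose epidermis the labels describe as guard cells, 2 of 3 measured guard cell genes rose and 3 of 5 photosynthesis genes fell. FAMA rose 6.30-fold and BLUS1 rose 10.2-fold, from 6.66 ± 0.27 to 10.01 ± 0.22 (SD, n = 3, adjusted p = 3.37e-05). GC1, at 2.03 ± 1.08, did not pass (adjusted p = 0.270), though it gave adjusted p = 0.00393 without spch replicate 4, an array outside the comparison that shares its estimate of the spread. When adjusted over the list alone, 2 of the 3 guard cell genes passed. The guard cell set test gave adjusted p = 0.000413, and adjusted p = 0.183 with an estimated correlation. Of the 3 measured stomatal lineage genes SPCH and MUTE rose, by log2 1.21 and at least 2.07, and EPFL9 differed by −1.23 (adjusted p = 0.0596, and 0.000878 with the replicate block), with 0.0189 without spch replicate 4 and 0.0435 without replicate 4 of the double mutant. All 3 passed when adjusted over the list alone, with opposite signs, and the set test gave adjusted p = 0.0714. That value was 0.0449 without WT replicate 3 and 0.0156 without scrm-D replicate 4.

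The largest rises in scrm-D were in AT2G43620, which encodes a chitinase family protein (64.5-fold, from 5.95 to 11.96), AT1G65500 (52.0-fold), AT4G22470 (32.8-fold) and the defensin gene PDF1.4 (AT1G19610, at least 28.4-fold). The expansin gene EXPA16 (AT3G55500) rose 29.6-fold and the lipase gene AT1G75880 rose 19.2-fold. The largest falls were in AT2G33850 (at least 29.1-fold, from 9.82 to 4.78) and the thionin gene AT1G66100 (22.5-fold), followed by EXPA8 (AT2G40610, 12.4-fold) and the thionin gene THI2.2 (AT5G36910, 12.2-fold). Of the 5 measured photosynthesis genes 3 fell, LHCB4.2 by 0.96, PRK (AT1G32060) by 0.93 and SBPASE (AT3G55800) by 0.91, the last 2 encoding enzymes of the Calvin cycle. LHCB4.1 (AT5G01530) and RCA (AT2G39730) differed by −0.34 and −0.27 without passing, and all 5 passed when adjusted over the list alone. The photosynthesis set test gave adjusted p = 0.000413, and adjusted p = 0.183 with an estimated correlation.

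DFR and UF3GT fell in scrm-D, with log2 changes of −2.75 and −2.26, and both passed when adjusted over the list alone. In the defence list PDF1.2 rose by 2.28 and WRKY53 (AT4G23810) by 1.39, while THI2.1 (AT1G72260) did not pass. All 3 passed when adjusted over the list alone, though THI2.1 read 4.42 and 4.74 in scrm-D and WT, both under the background level (set test, adjusted p = 0.191). WRKY53 gave adjusted p from 0.0530 to 0.106 without any 1 of WT replicates 3 and 4 and scrm-D replicates 2 and 4. In the auxin list IAA29 fell by at least 0.82, 2 of 3 passed when adjusted over the list alone, and the set test gave adjusted p = 0.0784, or 0.0322 without WT replicate 4. The 3 Aurora kinase genes differed by −0.02 to 0.05, PRL and CENH3 by −0.09 and −0.12, EXPA7 and EXPA18 by 0.15 and 0.18, and the 5 cold response genes by −0.59 to 0.21. No member of these 4 lists was called, none when adjusted over the list alone. The set test gave adjusted p = 0.947 for G2 and mitosis and 0.976 for cold response, the latter in the upward direction with a median of −0.00486.

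Between scrm-D and WT, limma called 3220 probe sets (14.2%), 1538 higher and 1682 lower, of which 583 and 425 changed at least 2-fold. Unlisted probe sets made up 1535 of the 3220. Without scrm-D replicate 4, 2127 were called. The 25S rRNA control read 9.60 ± 0.56 in scrm-D against 7.11 ± 0.49 in WT, and with it as a covariate the rise of SPCH was 0.97 ± 0.29 against 1.21 ± 0.23 (SE) without it, with adjusted p = 0.0540 from a smaller change and a wider error, and the auxin set test 0.0464.

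The double mutant, nearly all meristemoids per the labels, had the most probe sets changed from WT among the 3 mutants, with MUTE, SPCH, the 3 Aurora kinase genes and PRL among the rises. EXPA16 rose 95.2-fold, from 5.40 in WT to 11.97, and MUTE rose at least 56.6-fold, from 4.48 ± 0.05 to 10.78 ± 0.20 (SD, n = 3, adjusted p = 2.38e-09). AT5G07260, which encodes a START domain protein, rose at least 36.2-fold, from 3.90 ± 0.05 to 10.13 ± 0.23, and AT2G43620 rose 43.6-fold. The largest falls were in AT1G66100 (56.4-fold), AT2G33850 (at least 29.1-fold), THI2.2 (17.0-fold) and DFR (15.7-fold). The methionine sulfoxide reductase gene MSRB6 (AT4G04840) fell 11.2-fold. All 3 stomatal lineage genes passed, also when adjusted over the list alone: SPCH rose by log2 4.41, MUTE by at least 5.82, and EPFL9 fell by 2.29. The stomatal lineage set test gave adjusted p = 0.0349, and adjusted p = 0.275 with an estimated correlation. It was 0.0991 with the replicate block, 0.0575 without spch replicate 4 and 0.116 without replicate 4 of every genotype, a setting chosen after the data were seen.

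AUR1, AUR2 and AUR3 rose in the double mutant by 0.86, 0.78 and 0.96, and all 3 passed when adjusted over the list alone. The set test of G2 and mitosis gave adjusted p = 0.00998, and adjusted p = 0.223 with an estimated correlation. PRL rose by 0.71 and CENH3 differed by 0.45 (adjusted p = 0.0850, or 0.0482 without WT replicate 3), and both passed when adjusted over the list alone. FAMA fell by 1.01, while BLUS1 and GC1 differed by −0.59 and −2.65 with no call. Leaving out spch replicate 4 gave them adjusted p = 0.0191 and 0.000335, and GC1 gave 0.0446 with the replicate block. When adjusted over the list alone, 2 of the 3 guard cell genes passed, and the set test gave adjusted p = 0.0864, or 0.0118 without spch replicate 4 and 0.0111 without replicate 4 of every genotype. Of the 5 photosynthesis genes 4 fell, from LHCB4.1 by 0.46 to PRK by 0.86, and RCA differed by −0.23, with 5 passing when adjusted over the list alone. The photosynthesis set test gave adjusted p = 0.00402, and adjusted p = 0.223 with an estimated correlation.

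DFR and UF3GT fell in the double mutant by 3.98 and 3.07, and both passed when adjusted over the list alone. Of the 5 cold response genes COR47, a dehydrin, fell by 0.43, and 3 passed when adjusted over the list alone. COR15A and COR15B, at −1.91 and −2.01, gave adjusted p = 0.0569 and 0.0752, or 0.000723 and 0.00228 with the replicate block. COR15A read 8.32 in WT, 4.49 in spch, 7.53 in scrm-D and 5.77 in the double mutant on the replicate 4 arrays, the lowest of each genotype, where the hybridisation controls were also lowest (8.55, 9.04, 8.85 and 8.55). COR15A passed without replicate 3 of the double mutant (0.0413) or scrm-D replicate 3 or 4 (0.0462 and 0.0173). COR15B passed without WT replicate 4 (0.0351), replicate 2 of the double mutant (0.0452) or scrm-D replicate 4 (0.0331), and ZAT10, at −1.22, without WT replicate 3 (0.00267). The cold response set test gave adjusted p = 0.110, or 0.0458 with the block, 0.0213 without replicate 4 of every genotype and 0.0275 with the 25S rRNA covariate. GH3.3 fell by 0.98 and IAA29 by at least 0.82, 2 of 3 when adjusted over the list alone (set test, adjusted p = 0.127), and GH3.3 gave adjusted p = 0.0537 without replicate 2 of the double mutant. WRKY53 rose by 1.12, the only one of 3 defence genes to pass and 1 when adjusted over the list alone, and gave adjusted p = 0.0581 with robust moderation. Without any 1 of WT replicates 3 and 4, spch replicate 3, replicates 3 and 4 of the double mutant or scrm-D replicate 2, its adjusted p lay between 0.0542 and 0.156. The defence set test gave adjusted p = 0.947 in the downward direction, with a median of −0.26 and a mean of 0.07. EXPA7 and EXPA18 differed by −0.48 and −0.20 with no call, none when adjusted over the list alone.

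Between the double mutant and WT, limma called 6297 probe sets (27.7%), 3208 higher and 3089 lower, of which 786 and 871 changed at least 2-fold. Unlisted probe sets made up 2849 of the 6297. The 25S rRNA control read 9.62 ± 2.31 in the double mutant, with 6.96 on replicate 4, against 7.11 ± 0.49 in WT, and with it as a covariate 3736 probe sets were called and GH3.3 was −0.74 ± 0.31 against −0.98 ± 0.25 (SE) without it, with adjusted p = 0.139 from a smaller change and a wider error.

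**Figure D2:**
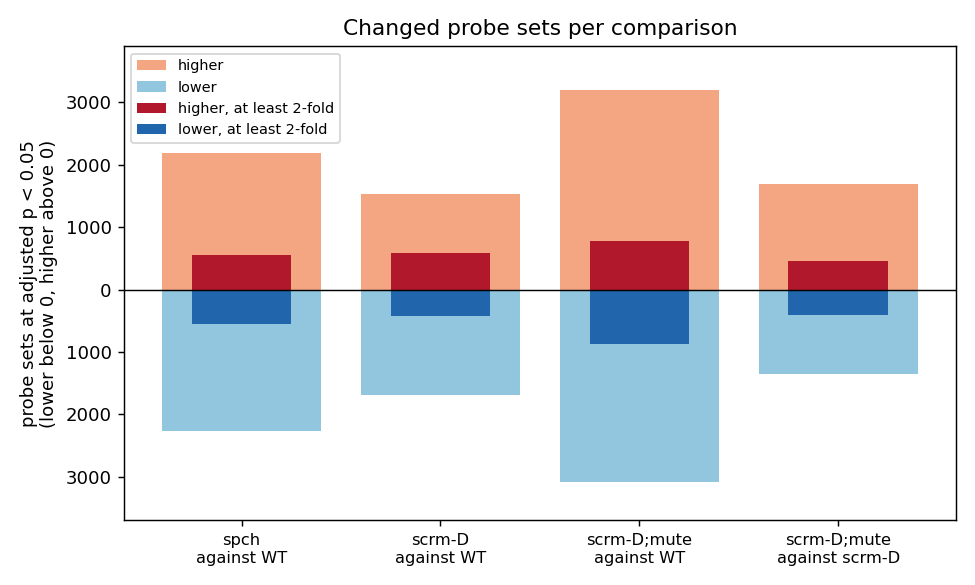
Number of probe sets called at an adjusted p under 0.05 in each comparison, higher above 0 and lower below 0, with those changed at least 2-fold as the darker inner bars. Of the 4 comparisons shown, that of scrm-D;mute with WT had the most calls, 6297 of 22746.

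The double mutant and scrm-D differ in their labelled genotype by the mute allele. The 3 measured guard cell genes were lower in the double mutant than in scrm-D, and SPCH, MUTE, the 3 Aurora kinase genes and PRL were higher. Of the guard cell genes, GC1 fell 25.6-fold, from 12.69 to 8.01, BLUS1 15.3-fold and FAMA 12.7-fold, and all 3 passed when adjusted over the list alone. The set test gave adjusted p = 2.47e-05, and adjusted p = 0.183 with an estimated correlation. SPCH rose 9.18-fold and MUTE 13.5-fold, while EPFL9 differed by −1.06 (adjusted p = 0.105, and 0.00231 with the replicate block), and all 3 passed when adjusted over the list alone. EPFL9 passed without spch replicate 4 (0.0394) or scrm-D replicate 4 (0.0349), and GC1 gave adjusted p = 0.0540 with robust moderation. The stomatal lineage set test gave adjusted p = 0.00998, adjusted p = 0.223 with an estimated correlation, and 0.0986 without replicate 4 of every genotype. AUR1, AUR2 and AUR3 rose by 0.84, 0.73 and 0.98, and all 3 passed when adjusted over the list alone. The set test of G2 and mitosis gave adjusted p = 0.00237, and adjusted p = 0.183 with an estimated correlation. AUR2 gave adjusted p from 0.0511 to 0.106 without any 1 of the double mutant arrays or of scrm-D replicates 3 and 4. PRL rose by 0.80 and CENH3 differed by 0.58 (adjusted p = 0.0547, and 0.0406 with the block), both passing when adjusted over the list alone. CENH3 gave 0.0385 without spch replicate 2 and 0.0309 without spch replicate 4.

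The largest rises over scrm-D were in AT4G28420, an aminotransferase gene (at least 13.3-fold, from 4.12 to 8.68), AT5G07260 (19.0-fold), RSU1 (AT3G48130, 17.6-fold) and AT2G22320 (at least 7.83-fold). The largest falls were in the lipase genes AT5G18430 (at least 31.2-fold) and AT1G75880 (at least 20.9-fold), AT5G25840 (30.0-fold) and GC1 (25.6-fold), followed by the malate transporter gene AT1G68600 (at least 11.1-fold). The defensin genes PDF1.2b (AT2G26020) and PDF1.2 fell, with log2 changes of −3.98 and −2.92, and the probe set of PDF1.2b is marked in its name as able to bind other transcripts. PDF1.2 was the only one of 3 defence genes to pass, also when adjusted over the list alone (set test, adjusted p = 0.185). Of the 5 cold response genes COR47 fell by 0.43 (adjusted p = 0.0532 without replicate 2 of the double mutant), and 2 passed when adjusted over the list alone. COR15A, COR15B, DFR and UF3GT, at −1.98, −1.42, −1.23 and −0.80, had no call, and gave adjusted p = 0.00112, 0.0265, 0.00111 and 0.00583 with the block. COR15A passed without scrm-D replicate 4 (0.00967), and DFR without WT replicate 4 (0.0493) or spch replicate 4 (0.0127). Of DFR and UF3GT, 1 passed when adjusted over the list alone. The cold response set test gave adjusted p = 0.0393, and adjusted p = 0.275 with an estimated correlation. It was 0.128 without replicate 4 of the double mutant, 0.0551 without scrm-D replicate 2 and 0.112 without scrm-D replicate 3. GH3.3 fell by 0.97 (2 of 3 auxin genes when adjusted over the list alone), a call that ended without any 1 of replicates 2 and 3 of the double mutant and replicates 2 and 4 of scrm-D, with adjusted p from 0.0621 to 0.104. GH3.5 (AT4G27260), at 0.51, passed without spch replicate 4 (0.0405) or replicate 4 of the double mutant (0.0234). The auxin set test gave adjusted p = 0.947 in the upward direction, with a median of 0.19 and a mean of −0.09. The 5 photosynthesis genes differed by −0.13 to 0.15 (set test, adjusted p = 0.947) and EXPA7 and EXPA18 by −0.63 and −0.38, with no call, none when adjusted over the list alone, and EXPA7 gave 0.0129 without scrm-D replicate 2.

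Between the double mutant and scrm-D, limma called 3046 probe sets (13.4%), 1695 higher and 1351 lower, of which 465 and 399 changed at least 2-fold. Unlisted probe sets made up 1379 of the 3046. Without replicate 2 of the double mutant 1968 were called, and without replicate 3 of it 1962. The 25S rRNA control read 9.60 ± 0.56 in scrm-D and 9.62 ± 2.31 in the double mutant.

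Lists with 1 measured member gave SIM (AT5G04470), an inhibitor of mitotic kinases, WSD1 (AT5G37300), an enzyme of wax ester synthesis, TRY (AT5G53200), a repressor of trichome fate, CLV3 (AT2G27250), the stem cell peptide, and GI (AT1G22770), a clock component. SIM fell in the double mutant against WT by 0.62, also when adjusted over the list alone. WSD1 passed there too (1 when adjusted over the list alone), but read 3.73 and 4.07, both under the background level of 4.95, so no fall can be read from it. Neither had a call in the other 3 comparisons, none when adjusted over the list alone. The SIM call ended without WT replicate 2 or 4 or replicate 2 or 3 of the double mutant (adjusted p from 0.0746 to 0.120), and the WSD1 call without WT replicate 3 or 4 or replicate 2 or 4 of the double mutant (0.0629 to 0.105). With the 25S rRNA covariate they gave 0.219 and 0.105, SIM from a smaller change with a wider error (−0.49 ± 0.25 against −0.62 ± 0.19 without it) and WSD1 from the wider error alone (−0.37 ± 0.14 against −0.34 ± 0.11). TRY, CLV3 and GI had no call in the 4 comparisons, none when adjusted over the list alone, with the widest differences of TRY and GI at −0.15 and −0.51. CLV3 lay under the background level of 4.95 in every genotype, so its lack of a call says nothing about it. GI gave adjusted p = 0.0358 in the double mutant against WT without spch replicate 4. No member of the abscisic acid list was analysed here.

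**Figure D3:**
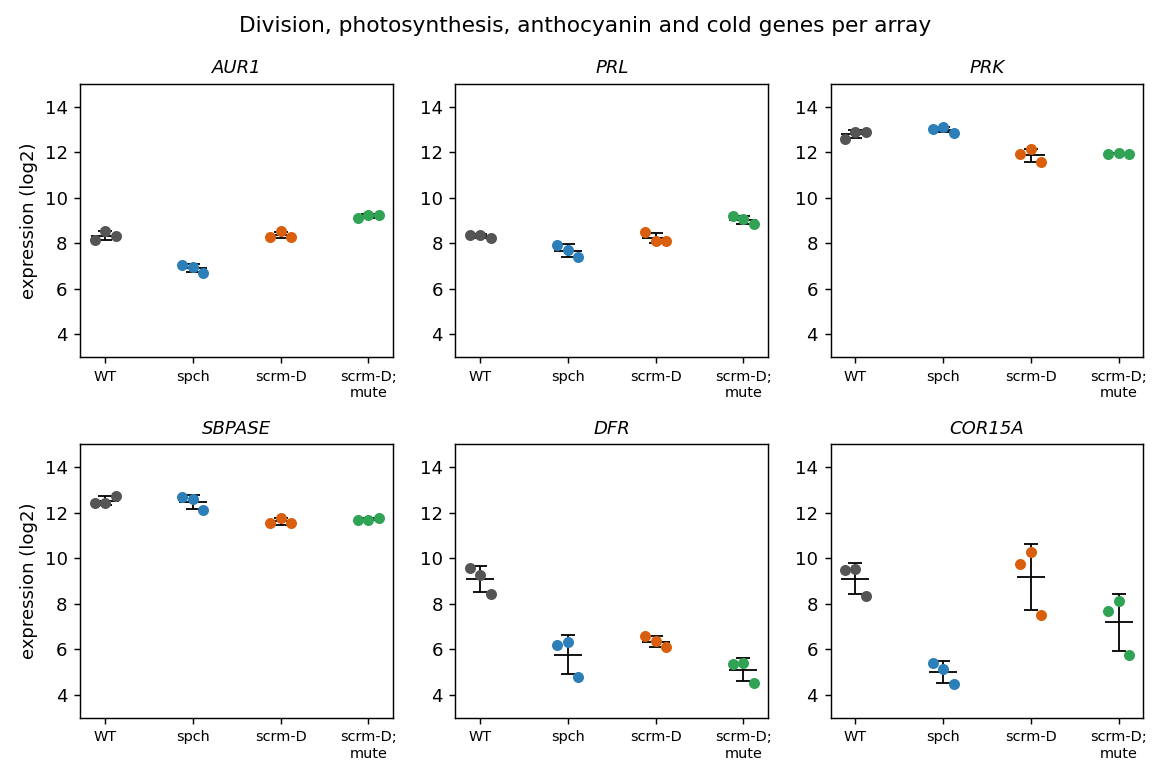
Expression (log2) of AUR1, PRL, PRK, SBPASE, DFR and COR15A on each array, with 1 point per array, the mean as a long line and 1 SD as bars (n = 3 per genotype). DFR was lower in all 3 mutants than in WT, and PRK and SBPASE were lower in scrm-D and scrm-D;mute than in WT.

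Probe sets were also counted by the genotype in which they stood above, or below, each of the other 3. In the double mutant 1083 probe sets were highest, 375 of them by at least 2-fold over every other genotype, and they included SPCH, MUTE, AUR1, AUR2, AUR3 and PRL. AT4G28420 stood at 8.68 ± 0.59 (SD, n = 3) there and between 3.91 and 4.12 in the other genotypes, and the kinase gene PID2 (AT2G26700) at 8.25 ± 0.20 and between 4.40 and 4.84. In scrm-D 389 were highest, 164 by at least 2-fold, and they included FAMA, BLUS1 and PDF1.2. AT4G18280 stood at 10.62 ± 0.13 there and between 6.73 and 6.96 elsewhere, and CHX20 (AT3G53720), a cation exchanger gene of guard cells, at 9.19 ± 0.29 and between 5.29 and 6.05. In spch 1170 were highest, 312 by at least 2-fold, with no member of the fixed lists. AT1G09500 stood at 7.63 ± 0.62 there and between 3.82 and 3.97 elsewhere, and PAP85 (AT3G22640), a seed storage protein gene, at 7.02 ± 1.48 and between 3.99 and 4.07. In spch 1113 were lowest, 165 by at least 2-fold, and they included SPCH, AUR1, AUR2, AUR3, PRL, CENH3, EXPA18 and COR15A. The peroxidase gene Prx37 (AT4G08770) stood at 5.59 ± 0.24 in spch and between 8.04 and 9.60 elsewhere. Without spch replicate 4, 666 probe sets were lowest in spch, and with the 25S rRNA covariate 532.

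The 3 comparisons with WT share its arrays. DFR, UF3GT and AT1G66100 were lower in all 3 mutants, as were 413 probe sets, and 183 were higher in all 3, against 22.7 and 20.8 for independent lists. The changes in scrm-D and the double mutant overlapped in 792 probe sets higher in both and 1407 lower in both, against 217 and 228 for independent lists, and 82 changed in opposite directions against 446. For spch and scrm-D the counts were 293, 457 and 414 against 148, 167 and 314, and for spch and the double mutant 541, 831 and 664 against 308, 307 and 615. The log2 changes of scrm-D and the double mutant had a covariance of 0.206 against 0.0142 in 20 simulated data sets with unchanged groups, a difference of 0.192, and those of spch differed from the simulated covariance by 0.0329 with scrm-D and by 0.0528 with the double mutant. The correlations were 0.661, 0.189 and 0.212 in the same order. The simulated correlation was about 0.50, which the shared WT gives where no probe set changes, so it is no benchmark for these. The 3 WT arrays cannot be split into parts of at least 2, so part of each excess may come from the shared control.

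**Figure D4:**
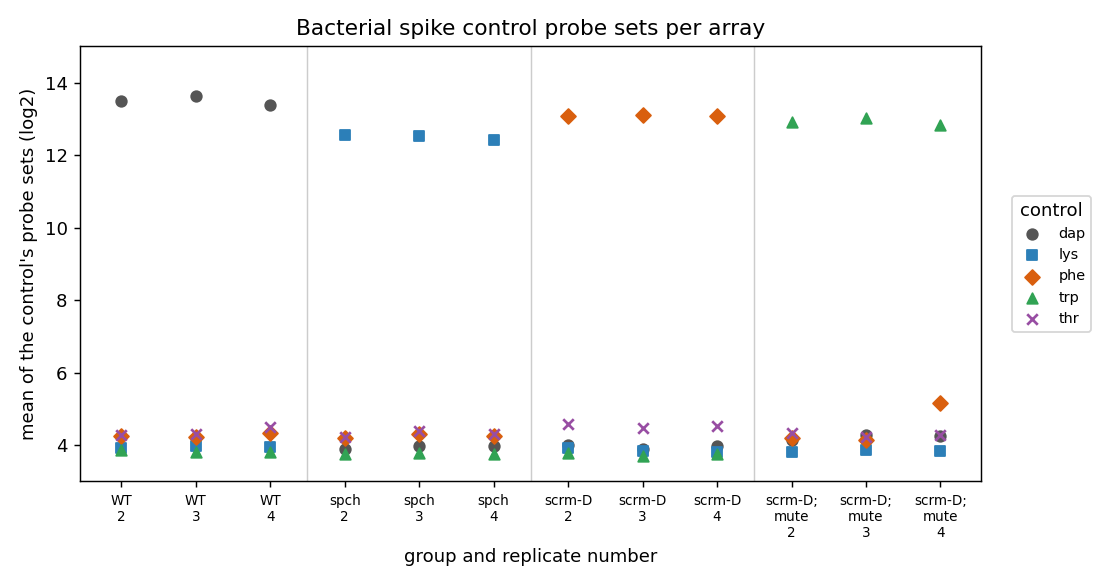
Mean log2 value of the probe sets of each bacterial control (dap, lys, phe, trp and thr) on each array, by genotype (n = 3 each). Each genotype had 1 control above 12.4, dap in WT, lys in spch, phe in scrm-D and trp in scrm-D;mute, and thr was low on all arrays.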

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

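The tests of replicate 4 of the double mutant given here were chosen only after its values had been seen, as were the assignments within replicate numbers, and the other counts over groupings of the arrays were planned. The comparisons leave out the bacterial control transcripts, which are added to a sample by hand and have no counterpart in the plant. The lys control read 12.5 on average in spch, phe 13.1 in scrm-D and trp 12.9 in scrm-D;mute, while each read at most 4.27 in the other genotypes, apart from phe in the double mutant. These 3 values were picked out because they lie above the level in WT, where dap read 13.5. Each labelled genotype thus had its own control on all 3 of its arrays, so no single array stood out as exchanged between genotypes after the controls were added. An exchange before that step, or of the labels of whole genotypes, would leave the same picture and was not tested with the controls. The guard cell genes GC1, BLUS1 and FAMA read 12.69, 10.01 and 9.56 in scrm-D, labelled as guard cells. In the double mutant they read 8.01, 6.07 and 5.89, which argues against an exchange of those 2 labels. The step at which the controls were added is not given in the sources used here. No biological explanation of the controls was tested, as the plant has none.

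On replicate 4 of the double mutant phe, the control of scrm-D, read 5.15, above its level of 4.27 in WT. That array also lay towards scrm-D in its genes: over 571 probe sets at least 2-fold higher in scrm-D it deviated from the other 2 arrays by a median of 0.38 log2, and over 544 that were lower in scrm-D by −0.27 (95% interval −0.31 to −0.26). Scrm-D material mixed in could raise the former but lower the latter by at most 0.03, so mixing at the share seen does not account for the lower genes. Over the 43 probe sets at least 8-fold higher in scrm-D, the median share of scrm-D signal was 1.74% (0.385% to 2.12%), against −0.378% and −0.265% in the other 2 arrays and 0.176% for phe (0.0859% to 0.397%). Only these 43 of the 571 higher probe sets were at least 8-fold higher. At a share of 2.12% a probe set under 8-fold would rise by less than 0.38. Mixing at the share seen thus does not account for the median of the 571 either. The bounds of genes and control overlap, so carry-over of labelled scrm-D material stays open for these 43, as does scrm-D material mixed in before the control was added, whose share had a lower bound of 0.385%. The slope towards scrm-D was 0.181 on this array and at most 0.0207 on replicate 4 of the other genotypes. The direction used for this array was scrm-D minus the other 2 double mutant arrays, so of replicate 4 it held only scrm-D. A shift common to the replicate 4 arrays thus enters it, but largely cancels in the direction used for WT and spch. The slopes therefore cannot decide whether such a shift is the whole cause. Deviations on replicate 4 of scrm-D and the double mutant correlated with r = 0.525. A difference between the seedlings of this replicate was not tested.

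Other groupings of the same arrays were counted beside the main counts. For each comparison of 2 genotypes there are 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. The real split gave 4442, 3220, 6297 and 3046 probe sets for spch, scrm-D and the double mutant against WT and the double mutant against scrm-D, the highest other 0, 0, 0 and 1, and in each case 1 of the 10, the real one, gave as many. For the patterns over 4 genotypes, 100 assignments of the 12 arrays were drawn, and 1 of them, the real one, gave as many probe sets in each pattern. Arrays of 1 genotype resemble each other, so draws that mix genotypes widen the spread and give fewer probe sets. The count thus shows only that arrays group by labelled genotype, which any cause that separates the genotypes would give. It also ignores the pairing by replicate number. The real counts were 1083 highest in the double mutant, 389 highest in scrm-D, 1170 highest in spch and 1113 lowest in spch, and the highest others 520, 24, 499 and 110. With 100 assignments drawn within each replicate number, 3, 8, 1 and 1 gave as many, and the highest others were 1170, 922, 1083 and 602. Each assignment that gave as many had put the 3 arrays of 1 genotype together in the group counted, and those that mixed genotypes there gave 0. These counts therefore set 1 genotype against another and cannot decide about chance.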

How the results depend on the processing

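Leaving out replicate 4 of every genotype, the 25S rRNA covariate and the list tests without single arrays were chosen only after the data had been seen, and the other settings were planned. No gene or list called with or without a setting turned its direction under it. Over 388 tests of named genes, the changes of call were 1 lost and 5 gained with median centring, 2 and 0 with quantile normalization, 0 and 8 of 308 without the dimmest 40% of probe sets, 5 and 2 with trend and robust moderation, 1 and 7 with array weights, 0 and 24 with the replicate block and 6 and 17 in fits of 2 genotypes. They were 41 and 0 at an adjusted p under 0.01, 11 and 30 without replicate 4 of every genotype, 34 and 8 with the 25S rRNA covariate, and 145 and 52 of 4656 without single arrays, and without the cross-hybridising probe sets 0 of 384 changed. Counts stayed within 1.5 times in the settings not named below. At an adjusted p under 0.01 the counts were 2282, 1627, 3670 and 1551 for spch, scrm-D and the double mutant against WT and the double mutant against scrm-D, and 644, 217 and 680 highest in the double mutant, scrm-D and spch and 503 lowest in spch, as a stricter limit must give fewer. With the 25S rRNA covariate 2108 changed in spch and 3736 in the double mutant against WT, and 532 were lowest in spch. The adjusted p of the guard cell list in spch was then 0.0903, of auxin in scrm-D 0.0464 and of cold in the double mutant against WT 0.0275. The replicate block gave counts of 5416, 4073, 7219 and 3956, adjusted p = 0.0991 for the stomatal lineage and 0.0458 for cold in the double mutant against WT, and changed no other list call. Without replicate 4 of every genotype the adjusted p was 0.0264 for cold in spch, 0.0213 for auxin in scrm-D, 0.116, 0.0111 and 0.0213 for the stomatal lineage, guard cells and cold in the double mutant against WT, and 0.0986 for the stomatal lineage in the double mutant against scrm-D. With an estimated correlation all 11 list calls ended: 0.294 for guard cells and 0.183 for mitosis in spch, 0.183 for guard cells and 0.183 for photosynthesis in scrm-D, 0.275, 0.223 and 0.223 for the stomatal lineage, mitosis and photosynthesis in the double mutant against WT, and 0.223, 0.183, 0.183 and 0.275 for the stomatal lineage, guard cells, mitosis and cold in the double mutant against scrm-D. Without single arrays the counts lay between 2955 and 4596 in spch, 2127 and 3496 in scrm-D, 1962 and 3333 in the double mutant against scrm-D, and 666 and 1102 lowest in spch. Adjusted p lay between 0.0156 and 0.117 for the stomatal lineage and 0.0322 and 0.112 for auxin in scrm-D, 0.0194 and 0.0575 for the stomatal lineage and 0.0118 and 0.128 for guard cells in the double mutant against WT, and 0.00819 and 0.128 for cold against scrm-D. Except for the stricter limit, the cause was not tested. The loss of an array lowers the number of arrays, but which array was lost also mattered. Without spch replicate 4 the counts rose to 3496 in scrm-D and 6570 in the double mutant against WT. In spch against WT 2955 were called without replicate 4 of spch, but 3617 and 3821 without its replicates 2 and 3. Median centring moved the median change by at most 0.07 and the share of higher calls in the double mutant against WT from 50.9% to 41.5%. List tests were not run under the scalings and filters, nor patterns in fits of 2 genotypes. Signal over background limits genes near 4.95, where 95% of absent controls lay below, so that small changes there cannot be read as folds.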

Other observations

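The grouping of genes by symbol and the list of starvation genes were chosen only after the data had been seen, whereas the predictions for that list were written before it was tested. Named genes were grouped by shared symbol into 39 families of at least 6 measured members, and each was tested as a set in the 4 comparisons (156 tests). Of the 29 SCPL genes, which encode serine carboxypeptidase-like proteins, 9 fell in spch, 9 in the double mutant and 5 in scrm-D against WT, and none rose (set test, adjusted p = 0.00418, 0.00418 and 0.0234, but 0.122, 0.122 and 0.248 with an estimated correlation). Of the 10 EXPA genes, which encode expansins that loosen cell walls, 6 passed as lower in spch (adjusted p = 0.00592, but 0.288 with an estimated correlation), with EXPA4 at −2.43 and EXPA15 at −1.79. Of these 6, EXPA7, EXPA8 and EXPA16 gave adjusted p = 0.418, 0.0514 and 0.262 with the 25S rRNA covariate, EXPA8 from a wider error alone (−1.54 ± 0.44 against −1.32 ± 0.34 without it), EXPA7 (−0.50 ± 0.33 against −0.92 ± 0.29) and EXPA16 (−0.61 ± 0.31 against −0.80 ± 0.24) from smaller changes with wider errors. Their calls also ended without single arrays: EXPA7 without any WT or spch array or replicate 3 of the double mutant (up to 0.148), EXPA8 without WT replicate 2 or 3 or spch replicate 4 (up to 0.0734), and EXPA16 without WT replicate 4 or any spch array (up to 0.0985). Of the 9 XTH genes, which encode enzymes that remodel xyloglucan, 4 fell in spch (adjusted p = 0.0261, but 0.288 with an estimated correlation), with XTH19 at −1.71 and XTH20 at −1.59, while XTH16 was −1.06 in spch and 3.02 in the double mutant. Of the 6 WRKY genes 3 rose in scrm-D (adjusted p = 0.0131, but 0.408 with an estimated correlation), WRKY6 by 2.07 and WRKY47 by 1.48 among them. Of the 8 CHR genes, for chromatin remodelling, 3 rose in the double mutant over scrm-D (adjusted p = 0.0131, but 0.408 with an estimated correlation), CHR17 by 0.99. Of the 8 ATG genes of autophagy 4 rose in the double mutant over WT (adjusted p = 0.0261, but 0.408 with an estimated correlation), ATG8B by 1.54. In all, 20 of the 156 tests passed at the preset correlation and 0 with an estimated one, and the median of no passing set changed sign under median centring or quantile normalization. Under the symbols PDF and GH the grouping mixed unrelated genes, and these were set aside.

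Glutaredoxin genes were among the largest rises in spch, and a candidate explanation is low carbon supply in seedlings whose epidermis, per the labels, holds pavement cells alone and so no stomata. Of the 5 named glutaredoxin genes, however, 4 also rose against WT in scrm-D, which the labels describe as guard cells: AT4G15680 by 2.53, AT4G15660 by at least 1.84, AT4G15700 by at least 1.81 and AT4G15690 by 1.58 on the log2 scale. In the double mutant AT4G15680, AT4G15660 and AT4G15690 rose, by 1.77, at least 1.36 and 1.28. The AT4G15690 call there ended without WT replicate 2 (adjusted p = 0.0510) and with the 25S rRNA covariate (0.0560, at 1.33 ± 0.43 against 1.28 ± 0.33, from the wider error alone). AT4G15700 did not pass there (adjusted p = 0.0723, but 0.0101 with the replicate block and 0.000689 without WT replicate 4). The rises in scrm-D weaken these 4 genes as a sign of absent stomata, provided its guard cells form working stomata, which was not tested. Those in the double mutant do not, as its epidermis is nearly all meristemoids per the labels. AT3G62950 had no call in either genotype. Of 27 listed genes that rise in darkness or sugar starvation, without those already seen, 4 were measured and all 4 rose in spch, MCCB (AT4G34030) by 1.14, AT2G32150 by 1.66, SEN5 (AT3G15450) by 2.06 and AT3G15630 by 1.19, each with all 3 spch arrays above all 3 of WT. The set test gave adjusted p = 0.000121 with a median of 1.43, but with an estimated correlation adjusted p = 0.0840, so the call is lost. In scrm-D and the double mutant against WT and in the double mutant against scrm-D it gave adjusted p = 0.475, 0.658 and 0.658, with MCCB higher (0.59, adjusted p = 0.0258) and AT2G32150 lower (−0.75, adjusted p = 0.0454) in the double mutant than in WT, and whether spch differs from them in this list was not tested. With an epidermis of nearly all meristemoids the double mutant would also have few stomata. Low carbon from absent stomata would then raise the list there too. The list was not called there, but its median was 0.46, and with 4 genes a missing call cannot show that it was not raised. With the 25S rRNA control as a covariate the median in spch was 1.35. A trend with that control at the slope seen within genotypes, which sets the covariate's slope, is thus not the whole cause. That slope rests largely on the double mutant, where the control varied most (SD 2.31 against 1.25 in spch). It read 6.96 there on replicate 4, the array that lay towards scrm-D, and 10.84 and 11.06 on the others. The covariate therefore cannot exclude a trend of another slope in spch. The difference in that control between WT and spch (7.11 and 9.63) cannot be separated from genotype, so its part stays open. The guard cell gene GC1 read 9.70 and 9.64 on spch replicates 2 and 3, so the absence of stomata rests on the label. With 4 genes, and with a control transcript in spch other than that of WT, other causes of such a response remain open.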
